A study of Mus musculus with 9 samples.

How the data were processed

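Single-cell RNA sequencing was done on brain microglia, the resident macrophages of the brain, from 9 mice aged 12 months on the C57BL/6J background. Per the labels, 3 mice were wild type (WT), 3 carried a knockout of 1 copy of C9orf72 (HET) and 3 carried a knockout of both copies (HOMO), with 2 females and 1 male in each genotype. The labels do not give the deleted part of the gene. Per the labels' protocols, the meninges were taken off, the brains were dissociated with papain, myelin was removed on magnetic beads, and cells bearing CD11b, a surface protein of microglia and other myeloid cells, were kept on magnetic beads. Each mouse gave 1 droplet-based library in which every captured transcript carried a unique molecular identifier (UMI). The labels place 3 mice on each of 3 process days. Day 1 held 1 mouse of each genotype, day 2 held 1 HET and 2 HOMO mice, and day 3 held 2 WT and 1 HET mouse, so HOMO and WT mice met on day 1 alone.

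The authors deposited a matrix of whole-number UMI counts per gene and barcode for each mouse, with no normalization. Per the submitters' processing notes, STAR 2.5.1, Cell Ranger 4.0.0, R 4.0.3 and Seurat 3.2.2 were used with the mm10 build. Which step each tool served, the gene annotation, the filter on cells and the treatment of doublets are not given in the sources used here. The matrices held 31342 genes and 30872 barcodes in all. The authors' deposited table of cells listed 26275 of these barcodes, and these were taken as the retained cells. Per the file headers, that table gives for each retained cell the percent of mitochondrial UMIs, a cluster number from 1 of 16 clusters, and an ARM and an IRM module score. ARM and IRM are read here as the activated-response and interferon-response states of microglia, after the genes in the deposited module lists. The authors' deposited scores have no fixed zero, so they were compared as differences. The table names no cell types, so the retained cells were analysed together and none was set apart as a non-microglial cell.

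UMI counts were summed per gene over the retained cells of each mouse, and mice were the replicates. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with genotype and sex in a single fit over the 9 mice, TMM scaling and the default filter on low counts by genotype, which left 12663 genes. Adjusted p-values are Benjamini-Hochberg values over those genes, and 0.05 was the threshold. Tests were two-sided, p-values across permutations included. A trend was fitted with the number of knockout alleles (0, 1 or 2) as a number in place of genotype. Levels are CPM, counts scaled by library size, of the TMM-scaled library, except for C9orf72 per mouse, where they are the CPM of the mouse's own total, without that scaling. Intervals on UMI counts are exact Poisson intervals at 95% and cover counting error only. A gene with 0 UMIs in a mouse could have had a level up to that of 3 UMIs, which was 0.0972 CPM in the deepest library and 0.220 CPM in the shallowest.

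No cluster qualified as homeostatic microglia by the fixed markers. In place of that state, 4 clusters with no gene above a fold of 4 over the other cells (clusters 0, 2, 4 and 5) were grouped and are called the baseline clusters. This limit on the fold was set after the data were seen. The group is not a homeostatic class by its markers. Homeostatic markers averaged a log2 of 0.0214, -0.161, -0.0233 and 0.188 over all cells in clusters 0, 2, 4 and 5. They averaged 0.377 in cluster 6 and 0.145 in cluster 9, which are outside the group. Cluster 13 was called interferon-response-like and cluster 11 activated-response-like, since markers of that class averaged a log2 of more than 1 above all cells and at least 3 of them were among the 10 leading genes. Leading genes had at least 30 CPM in a cluster and were ranked by fold with a pseudocount of 5 CPM. Shares of cells and mean scores per mouse were compared by exact permutation of the genotypes over mice. For 3 mice against 3 the smallest possible p is 0.1. For the slope over knockout alleles the 9 mice have 1680 arrangements, which allow a p of 0.00119. Benjamini-Hochberg values were taken over these 5 results.

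Gene lists were tested with camera of limma 3.58.1 on voom values of the sums per mouse, with sex in the model and a preset correlation between genes of 0.01. Of 38 lists fixed before the data were examined and the authors' ARM and IRM modules, 39 had at least 3 measured genes. Each camera result stands beside the same test with a correlation estimated per list. Between HOMO and WT the estimate was -0.00745 for chemokines and -0.00477 for mTORC1, under the preset value, yet neither list passed with it. Not passing with an estimated correlation therefore does not by itself show that the members of a list moved together. The fry test of limma was run too, for a change on balance in 1 direction and for a change in either direction. The 2 deposited modules were chosen by the study, so they are no independent evidence for their own direction.

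The genes named were chosen by a rule set before the data were examined. C9orf72 was named in every comparison. Between HOMO and WT the rule took up to 10 higher and 10 lower genes with the largest change among those with an adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the mice of the groups. For the other pairs it took up to 6 in each direction, and for the trend the 5 higher and 5 lower with the smallest p. In each list that passed camera it took up to 4 members with the smallest p. Where under 5 genes passed, the 5 smallest p were named as not having passed. Transcripts of X inactivation, Y-linked genes and provisional gene models were counted but not named, except where said. Positions come from GENCODE release 21 of the mouse on GRCm38, which gave a position for 31195 of the gene IDs (99.5%). The UMI counts were not stated to use strand, so overlapping genes may share reads.

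The test was checked on simulated counts drawn from the real means and library sizes, with 200 of 12549 genes changed. The changed genes were drawn only from those with a mean of at least 10 CPM. Genes were simulated independently, with no shift by day or sex shared between them. The rates below therefore do not hold for genes at lower levels or for shifts shared between mice. Between HOMO and WT it recovered 86% of changes of 0.5 on the log2 scale and 100% of changes of 1, with 14 false calls among 200. HET mice were given 0.5 times the log2 change of HOMO mice, and the test then recovered 8% and 71% of the same genes between HET and WT and 9% and 67% between HOMO and HET. For the trend it recovered 84% and 100%. No pair of libraries of a genotype agreed within sampling noise: the chi-square per gene was at least 4.30, and none was a duplicate. The alternatives tried were DESeq2 1.42.0, median-ratio scaling, no filter on low counts, no covariate, process day in place of sex or beside it, a block for the replicate number, only the groups compared, females only, each mouse left out in turn, counts thinned to equal totals, and every barcode in the matrices. For shares, cells were also clustered anew with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 components, 20 neighbours, resolution 0.8). Fits without the clusters led by markers of other cells (6, 14 and 15) were added after the data were seen.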

Results

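The transcriptomes of CD11b-selected brain cells were compared between 3 WT, 3 HET and 3 HOMO mice to ask how the loss of 1 or both copies of C9orf72 changes microglia of aged animals. The retained cells numbered 2842, 2709 and 1766 in the WT mice, 2228, 3154 and 2598 in the HET mice, and 3034, 4328 and 3616 in the HOMO mice. Their summed depth ran from 13628495 UMIs in WT replicate 3 to 30870224 UMIs in HOMO replicate 2. The median cell held 7901 ± 167 UMIs in WT, 7687 ± 235 in HET and 6713 ± 354 in HOMO mice (mean of the medians ± SD, n = 3 each), so cells of HOMO mice were shallower. The share of barcodes retained was lowest in HOMO replicate 1, at 75%.

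C9orf72 (ENSMUSG00000028300, chromosome 4, 35191285 to 35226175 on GRCm38) encodes a protein of a complex with Smcr8 and Wdr41 that acts in membrane traffic and autophagy. It was measured at 24.0, 24.6 and 24.2 CPM in the 3 WT mice, at 13.2, 12.8 and 12.3 CPM in the HET mice, and at 0.295, 0.0324 and 0.107 CPM in the HOMO mice. The HOMO values rested on 7, 1 and 3 UMIs, against 330 to 583 UMIs in each WT mouse. Pooled over mice, HOMO cells held 0.548% of the WT level, with a counting interval of 0.273% to 0.983%. HET mice held 52.6% of the WT mean, 12.8 ± 0.479 against 24.3 ± 0.278 CPM (mean ± SD, n = 3 each), and the groups did not overlap. In edgeR the log2 fold change was -7.41 between HOMO and WT (SE 0.237, adjusted p = 7.5e-08) and -6.50 between HOMO and HET (SE 0.248, adjusted p = 5.03e-07). Between HET and WT it was -0.91 (SE 0.132) and did not pass in edgeR over the 9 mice (adjusted p = 0.116). It passed with DESeq2 (adjusted p = 3.64e-07), without the filter on low counts (adjusted p = 0.0133) and in a fit of those 2 groups alone (adjusted p = 0.00974). Within day 1 the log2 ratio was -6.34 for HOMO over WT and -0.85 for HET over WT, and within day 3 it was -0.99 for HET over WT. The library of each mouse matched its genotype label in its C9orf72 level, although whether the counted 3′ ends lie in the deleted part is not known.

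**Figure D1:**
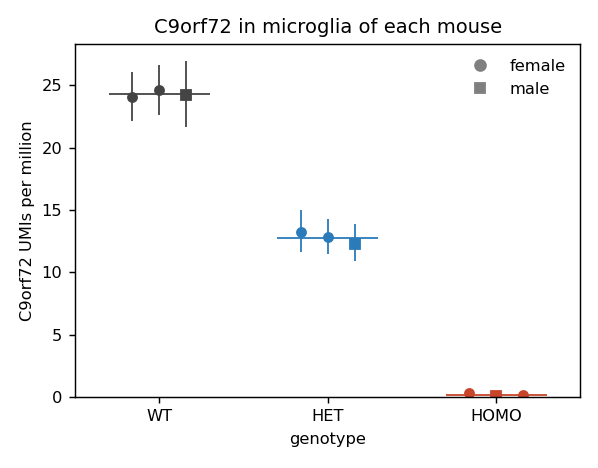
C9orf72 level (vertical axis, CPM of the mouse's own total) in the 9 mice by genotype (horizontal axis). Points are mice, circles females and squares males, vertical bars are exact 95% Poisson intervals that cover counting error only, and horizontal lines are group means; the 3 HET mice lay between 12.3 and 13.2, and the 3 HOMO mice at or below 0.295.

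Microglia of HOMO mice differed from those of WT mice in a small set of genes that included Cst7, Cd63, Hebp1, Nlrp3 and Ide. Cst7, which encodes cystatin F, an inhibitor of lysosomal cysteine proteases, rose to 35.7 ± 4.44 CPM from 20.2 ± 1.94 CPM (mean ± SD, n = 3 each), a fold of 1.75. Cd63, a tetraspanin of late endosomes and lysosomes, rose to 657 ± 7.67 from 468 ± 32.5 CPM, and Hebp1, which encodes a haem-binding protein, rose to 103 ± 6.34 from 70.7 ± 0.846 CPM. Nlrp3, the sensor of an inflammasome that activates caspase-1, fell to 69.4 ± 5.70 from 113 ± 14 CPM. Ide, which encodes the insulin-degrading enzyme that also cleaves amyloid-β peptide, fell to 19.5 ± 1.21 from 30.1 ± 2.92 CPM. This gene is also on the list of C57BL/6 substrain differences, so a strain difference between the mice cannot be told apart from the knockout for it.

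The edgeR test found 30 genes past the threshold among 12663, 11 higher and 19 lower in HOMO mice, and 1646 genes (13%) had an unadjusted p under 0.05. Apart from C9orf72, the rule named 6 higher and 9 lower genes. Of these named genes the largest rise was in Chst2, a carbohydrate sulfotransferase gene, from 8.03 ± 1.34 to 19.0 ± 5.87 CPM (log2 fold change 1.22, SE 0.187, adjusted p = 0.0388). Cst7 rose by 0.80 on the log2 scale (SE 0.103, adjusted p = 0.0171) and Hebp1 by 0.54 (SE 0.0571, adjusted p = 0.00664). Cd22, a sialic-acid-binding receptor, rose by 0.55 (adjusted p = 0.0461), Cd63 by 0.49 and Anxa5, which encodes annexin A5, by 0.43 (adjusted p = 0.0404 each). Among the lower genes, Nlrp3 changed by -0.69 (SE 0.0839) and Mir142hg, the host transcript of the blood-cell microRNA miR-142, by -0.66 (SE 0.0813), both with an adjusted p of 0.0154. Hlf, a circadian-type transcription factor gene, Ide and Fry changed by -0.68, -0.63 and -0.50 (adjusted p = 0.0182 each). Nhsl2 (-0.71, adjusted p = 0.0397), Ccnd1, which encodes the cell cycle regulator cyclin D1 (-0.52, adjusted p = 0.0415), Khdrbs3 (-0.51, adjusted p = 0.0425) and the B-cell adaptor gene Bank1 (-0.42, adjusted p = 0.0415) were also lower. Bank1 overlaps a provisional gene model that passed in the same direction, so their reads cannot be told apart here.

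**Figure D2:**
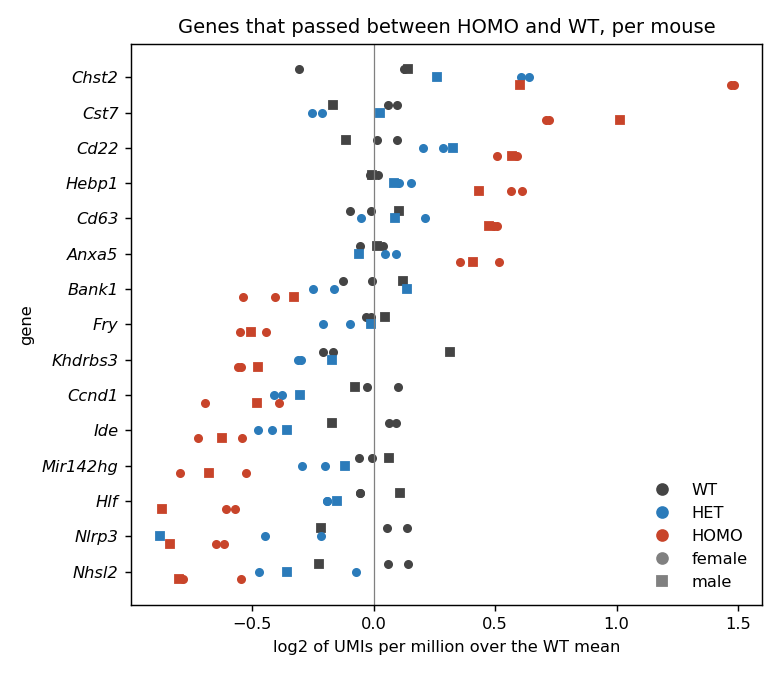
Level of the 15 named genes other than C9orf72 that passed between HOMO and WT (vertical axis), as log2 of the CPM over the mean of the 3 WT mice (horizontal axis). Each point is 1 mouse, coloured by genotype, with circles for females and squares for males. For each gene the 3 HOMO mice lie on 1 side of the 3 WT mice, as the naming rule required.

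HOMO and WT shared day 1 alone, with 1 female HOMO and 1 male WT mouse that are also part of the pooled fit. The log2 ratio between them was 0.89 for Cst7, 0.61 for Hebp1, 1.33 for Chst2, -0.43 for Nlrp3 and -0.55 for Ide. With process day beside sex 80 genes passed, 17 higher and 63 lower, 19 of the 30 among them. With process day in place of sex 60 passed, 13 higher and 47 lower, only 14 of the 30 among them. The count was 150 with DESeq2, 79 higher and 71 lower, 64 without the filter on low counts, 13 with only these groups and 3 with every barcode. It was 3 without WT replicate 1, 2 without WT replicate 2 and 134 without WT replicate 3. It was 8 without HOMO replicate 1, 16 without HOMO replicate 2 and 3 without HOMO replicate 3. Every named gene kept its direction in these fits, which the rule of no overlap between the mice of the groups nearly ensured. Across 19 alternative fits Cd63 and Anxa5 passed in 8, Bank1 and Cd22 in 7, Chst2 in 10, Ide and Nlrp3 in 12, Cst7 in 14 and Hebp1 in 16. The mice of the groups did not overlap in 2512 genes (19.8%), where chance gives 10%.

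Among the gene lists fixed in advance, lysosomal genes were called higher in HOMO than in WT mice by camera, but not with an estimated correlation (adjusted p = 0.645). Of 50 measured lysosomal genes 45 were higher and 5 lower; 1 passed over all genes (Cd63), 49 did not pass, and 9 passed, all higher, when adjusted over the list alone. The camera test gave an adjusted p of 3.66e-10 for this list (adjusted p = 0.645 with an estimated correlation). Members that did not pass over all genes were Ctsa (0.36, adjusted p = 0.0741) and Npc2 (0.32, adjusted p = 0.0943), which encode the protective protein cathepsin A and a cholesterol carrier. Of 65 measured nuclear genes of oxidative phosphorylation 61 were higher, none passed over all genes, and 1 passed adjusted over the list alone. The camera adjusted p was 3.66e-10, and adjusted p = 0.645 with an estimated correlation. Ndufb9, of respiratory complex I, was at 166 ± 6.86 against 138 ± 2.5 CPM (adjusted p = 0.0943). Of 79 cytosolic ribosomal protein genes 68 were higher, and none passed over all genes or adjusted over the list alone. The camera adjusted p was 4.33e-11, and adjusted p = 0.645 with an estimated correlation. Rpl19 was at 1931 against 1633 CPM (log2 0.24), while Rps10 was lower at 311 against 397 CPM (log2 -0.34).

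Lists of activated microglia leaned higher in HOMO mice, but their members went both ways. Of 32 measured genes of disease-associated and activated microglia 2 rose (Cst7 and Cd63) and 30 did not pass, while 8 higher and 3 lower passed adjusted over the list alone. The camera test called the list higher (adjusted p = 0.0392; adjusted p = 0.674 with an estimated correlation), and its median log2 fold change was 0.12 while its mean was -0.12, so they differed in sign. With process day in the model this list did not pass (adjusted p = 0.0908). Lyz2 (0.49, adjusted p = 0.0570) and Ctsz (0.31, adjusted p = 0.0961) were higher without passing. Of the 65 measured genes of the authors' ARM module, which the study chose and which is therefore no independent evidence, 3 rose (Cst7, Cd63 and Anxa5) and 62 did not pass; 14 higher and 4 lower passed adjusted over the list alone. The module's camera adjusted p was 8.42e-05, with adjusted p = 0.674 with an estimated correlation and 0.874 with process day in the model. The homeostatic list did not pass (adjusted p = 0.306), nor did autophagy (adjusted p = 0.749) or the partners of C9orf72 (adjusted p = 0.471), where the log2 fold change was -0.03 for Smcr8 and 0.26 for Wdr41 (adjusted p = 0.205), neither of which passed.

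Interferon-response genes were also called higher in HOMO than WT mice, but not with an estimated correlation (adjusted p = 0.704), and no single member passed. Of 46 measured genes of the type I interferon response 39 were higher and 7 lower, and none passed over all genes or adjusted over the list alone. The camera adjusted p was 1.61e-05, and adjusted p = 0.704 with an estimated correlation. Ifitm3, an antiviral membrane protein gene, was at 51.1 and 54.4 CPM in HOMO replicates 1 and 3 but at 28.7 CPM in HOMO replicate 2, against 29.6 to 33.3 CPM in WT mice (log2 0.48, adjusted p = 0.251). Oasl2 showed the same order, with 8.36, 3.84 and 8.4 CPM in the HOMO mice and a mean of 3.74 ± 0.283 CPM in WT mice. Of the 86 genes of the authors' IRM module, again chosen by the study, 68 were higher and none passed over all genes or adjusted over the list alone. The camera adjusted p was 4.57e-06, and adjusted p = 0.685 with an estimated correlation. MHC class I genes were higher in 19 of 22 (camera adjusted p = 0.000555; adjusted p = 0.685 with an estimated correlation), with Psme2 at 133 ± 7.51 against 112 ± 1.96 CPM, and none passed over all genes or adjusted over the list alone. The MHC class I list did not pass with process day in the model (adjusted p = 0.173).

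Chemokine genes and genes of the unfolded protein response were called lower in HOMO than WT mice, but not with an estimated correlation (adjusted p = 0.302 and 0.674). For chemokines that estimate was -0.00745, under the preset 0.01, so the higher adjusted p does not show that these genes moved together. Of 19 measured chemokine and chemokine receptor genes 17 were lower, none passed over all genes, and 4 passed, all lower, adjusted over the list alone (camera adjusted p = 0.000555; adjusted p = 0.302 with an estimated correlation). Ccl24 was at 4.72 ± 0.298 against 8.45 ± 1.66 CPM, and Ccl2 at 55.9 ± 8.59 against 119 ± 50 CPM. Of 22 genes of the unfolded protein response 20 were lower, and none passed over all genes; 1 passed adjusted over the list alone (camera adjusted p = 0.00399; adjusted p = 0.674 with an estimated correlation). Chac1, a glutathione-degrading enzyme gene induced by that response, was near the floor at 0.065 ± 0.0523 against 0.574 ± 0.133 CPM (adjusted p = 0.0700). Of 33 genes of mTORC1 and amino acid sensing 26 were higher and none passed over all genes or adjusted over the list alone (camera adjusted p = 0.00668; adjusted p = 0.302 with an estimated correlation), with Lamtor1 and Lamtor3 of the Ragulator complex at 0.17 and 0.18 on the log2 scale. Between HOMO and WT 11 lists passed camera, and as many passed in 5 of 10 splits of these mice, the real one included. The other 28 of the 39 lists did not pass, and no list passed with an estimated correlation in this comparison. Of these 28 lists 8 passed with process day in the model, among them immediate early genes (adjusted p = 0.00179), heat shock (adjusted p = 0.00208) and inflammatory cytokines (adjusted p = 0.000872). All 9 measured neutrophil markers were higher in HOMO mice without passing as a list (camera adjusted p = 0.0715), though the list passed with process day in the model (adjusted p = 0.00117); S100a8 and S100a9 together were at 389 CPM in HOMO replicate 1, 36.7 CPM in HOMO replicate 3 and 235 CPM in WT replicate 2, against 7.78 to 19.3 CPM in the other 6 mice. Of other cell markers that did not pass as lists, all 5 erythroid genes (median log2 -3.44) and 9 of 11 neuronal genes were lower in HOMO than WT mice. The camera test gave the erythroid list the other sign (adjusted p = 0.946). Erythroid markers together were at 421 CPM in HOMO replicate 2, and at 1.01 and 1.21 CPM in HOMO replicates 1 and 3. They were at 350 and 526 CPM in WT replicates 1 and 2, and at 2.86 CPM in WT replicate 3. Their level thus followed single mice within each genotype.

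Within the baseline clusters, which held 45.5% of the retained cells, HOMO mice again differed from WT mice, with Lyz2 and Apoe among the genes that rose. Lyz2, which encodes a lysozyme of myeloid cells, rose to 584 ± 45.9 from 380 ± 35.0 CPM (log2 fold change 0.62, adjusted p = 0.00362). Apoe, the lipid carrier apolipoprotein E, rose to 587 ± 174 from 255 ± 67.9 CPM (1.24, adjusted p = 0.0315). Slc29a3, a lysosomal nucleoside transporter gene, fell to 128 ± 8.90 from 234 ± 28.9 CPM (-0.88, adjusted p = 0.0299), and Igf1r, the receptor of insulin-like growth factor 1, fell to 44.0 ± 4.03 from 61.2 ± 1.29 CPM (-0.48, adjusted p = 0.0299). These 4 genes were singled out after their values were seen.

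In these clusters 36 of 11663 genes passed, 16 higher and 20 lower, with 1363 at an unadjusted p under 0.05, and 22 of the 36 had also passed over all retained cells. C9orf72 (-7.54), Nlrp3 (-0.70), Chst2 (1.44), Ide (-0.66), Hebp1 (0.52), Cst7 (0.95), Cd63 (0.48) and Anxa5 (0.55) were among the 22. Apoe, Chst2, Cst7 and Lyz2 were also among the 10 leading genes of cluster 3, which is outside the baseline clusters. The count was 73 with DESeq2, 315 without the filter, 109 with process day beside sex (16 of the 36 among them) and 17 with only these groups. With process day in place of sex 47 passed, only 8 of the 36 among them. It was 8 without WT replicate 1, 9 without WT replicate 2, 148 without WT replicate 3, 14 without HOMO replicate 1, 24 without HOMO replicate 2 and 15 without HOMO replicate 3.

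The comparison of HET with WT mice asked whether the loss of 1 copy is enough to change microglia, and no gene passed in edgeR. The count was 0 of 12663 genes, with 607 at an unadjusted p under 0.05 and 9 past the threshold in DESeq2. In the simulated counts this comparison recovered 8% of the genes given a log2 change of 0.5 between HOMO and WT. A count of 0 therefore does not show that the loss of 1 copy leaves microglia unchanged. The smallest p-values belonged to genes that did not pass, C9orf72 itself among them (log2 fold change -0.91, adjusted p = 0.116). Dnaaf3 was at 8.65 ± 0.340 CPM in HET and 5.01 ± 0.397 CPM in WT mice (log2 fold change 0.79, adjusted p = 0.116). Hspa1a, an inducible heat shock protein gene, was at 261 ± 68.8 against 167 ± 41.0 CPM (0.64, adjusted p = 0.146), and Nbea at 24.2 ± 5.76 against 15 ± 3.08 CPM (0.67, adjusted p = 0.208). Nlrp3 was at 80.1 ± 17.9 against 113 ± 14 CPM (-0.50, adjusted p = 0.208), with a log2 ratio of 0.00 within day 1 and -0.98 within day 3. The mice did not overlap in 1230 genes (9.71%), where chance gives 10%. The count was 6 without the filter, 2 with process day in place of sex or beside it, 2 with only these groups and 2 without WT replicate 2.

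Of the 39 gene lists 8 passed camera between HET and WT mice, 3 higher and 5 lower, and none held with an estimated correlation. As many lists passed in 9 of 10 splits of these mice, the real one included. Genes of oxidative phosphorylation (53 of 65 higher; adjusted p = 0.00659, and adjusted p = 0.771 with an estimated correlation), heat shock proteins and chaperones (13 of 20 higher; 0.00706 and 0.771) and the lysosome (39 of 50 higher; 0.0112 and 0.771) were called higher. The lists of C57BL/6 substrain differences (6 of 6 lower; 0.00659 and adjusted p = 0.736 with an estimated correlation), cholesterol synthesis (18 of 24 lower; 0.0112 and 0.771), monocytes (7 of 9 lower; 0.0122 and 0.771), the unfolded protein response (18 of 22 lower; 0.0233 and 0.771) and border macrophages (10 of 11 lower; 0.0348 and 0.771) were called lower. No member passed over all genes, and 4 passed adjusted over the list alone, 1 higher and 3 lower. Ccr2, a monocyte chemokine receptor, was at 4.51 ± 0.112 against 7.08 ± 1.25 CPM, and Ide, a member of the substrain list, at 22.6 ± 0.937 against 30.1 ± 2.92 CPM (adjusted p = 0.407). All 9 neutrophil markers (median log2 -2.37) and all 5 erythroid markers (-2.64) were lower in HET mice without passing as lists. For the erythroid list camera again gave the other sign (adjusted p = 0.634). Neutrophil markers together were at 547 CPM in WT replicate 2. They were at 236 and 217 CPM in WT replicates 1 and 3, and at 214 to 226 CPM in HET mice. S100a8 and S100a9 alone were at 235 CPM in WT replicate 2, 7.78 and 10.9 CPM in WT replicates 1 and 3, and 10.1 to 19.3 CPM in HET mice. Outside WT replicate 2, most of the summed level thus came from other members of the list. Erythroid markers together ran from 2.86 to 526 CPM in WT and from 1.91 to 263 CPM in HET mice, so the groups overlapped. Of these 8 lists only the unfolded protein response passed with process day in the model (adjusted p = 0.000313), where 8 others passed that had not passed without it, the ARM module (adjusted p = 0.000325) and inflammatory cytokines (adjusted p = 0.00253) among them.

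The comparison of HOMO with HET mice asked what the loss of the second copy adds, and Cst7 was the gene that rose. It was at 35.7 ± 4.44 CPM in HOMO and 18.3 ± 1.97 CPM in HET mice (log2 fold change 0.96, SE 0.103, adjusted p = 0.0107). Its log2 ratio was 0.93 within day 1 and 1.12 within day 2. C9orf72 was the other gene that passed, so 2 of 12663 genes did, with 1211 at an unadjusted p under 0.05 and 32 past the threshold in DESeq2. Hebp1 was at 103 ± 6.34 against 76.5 ± 1.94 CPM (0.42, adjusted p = 0.0613), Sema6d, a semaphorin gene, at 3.37 ± 0.821 against 7.29 ± 0.517 CPM (-1.11, adjusted p = 0.0835) and Lyzl4 at 3.07 ± 0.247 against 5.65 ± 0.709 CPM (-0.88, adjusted p = 0.179), none of which passed. The mice did not overlap in 2132 genes (16.8%), where chance gives 10%. The count was 4 without the filter and in females, 6 with process day in place of sex, 7 with it beside sex, and 1 with every barcode. It was 5 without HOMO replicate 2 and 1 without HET replicate 2, HET replicate 3, HOMO replicate 1 or HOMO replicate 3, where C9orf72 alone passed. Without HET replicate 1 the count stayed at 2, and Cst7 did not pass (adjusted p = 0.0849).

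Of the 39 gene lists 17 passed camera between HOMO and HET mice, 12 higher and 5 lower, and none held with an estimated correlation. Called higher were the cytosolic ribosomal proteins (65 of 79 higher; adjusted p = 5.18e-12, and adjusted p = 0.546 with an estimated correlation), the authors' ARM module (48 of 65 higher; 3.89e-08 and 0.546), the lysosome (40 of 50; 3.2e-06 and 0.546), the authors' IRM module (72 of 86; 5.76e-06 and 0.624) and the type I interferon response (40 of 46; 7.96e-05 and 0.674). In the ARM module 1 gene rose, 64 did not pass, and 13 passed, all higher, adjusted over the list alone; the study chose both modules, which are no independent evidence. Heat shock proteins and chaperones were lower in 17 of 20, with 5 past the threshold adjusted over the list alone (3.11e-05; adjusted p = 0.546 with an estimated correlation): Hspa1a was at 179 ± 55.9 against 261 ± 68.8 CPM and Hsph1 at 13.9 ± 0.701 against 18.9 ± 1.17 CPM. The homeostatic list was lower in 22 of 31 (0.0167; adjusted p = 0.612 with an estimated correlation), with Fcrls at 1703 ± 137 against 1989 ± 28.3 CPM and Tgfbr1 at 702 ± 2.09 against 812 ± 14 CPM. Chemokines and the cell cycle were called lower (0.0172 each; adjusted p = 0.546 each with an estimated correlation), as were neuronal markers (0.0258; adjusted p = 0.560 with an estimated correlation), while glycolysis, oxidative phosphorylation, MHC class I, oxidative stress, disease-associated, monocyte and neutrophil lists were called higher (adjusted p = 0.0303 or less each; adjusted p = 0.546 or, for MHC class I, 0.624 with an estimated correlation). The disease-associated list had a median of 0.07 and a mean of -0.07, which differ in sign. With process day in the model 15 of the 17 lists passed, and neuronal markers (adjusted p = 0.199) and oxidative stress (adjusted p = 0.144) did not. In the neutrophil list 9 of 9 genes were higher, and S100a8 was at 66.1 ± 98.4 CPM in HOMO and 5.33 ± 1.92 CPM in HET mice. Neutrophil markers together were at 747 CPM in HOMO replicate 1, but at 219 and 266 CPM in HOMO replicates 2 and 3. They were at 214 to 226 CPM in HET mice. S100a8 and S100a9 alone were at 389, 9.30 and 36.7 CPM in HOMO replicates 1, 2 and 3, and at 10.1 to 19.3 CPM in HET mice.

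Over 0, 1 and 2 knockout alleles, the slope passed for several of the genes that differed between HOMO and WT mice. A slope that passed does not show a step at 1 allele. Per allele, Hebp1 rose by 0.27 on the log2 scale (SE 0.0369) and Nlrp3, Mir142hg and Ide changed by -0.35, -0.33 and -0.32 (SE 0.0469, 0.0449 and 0.0435), each with an adjusted p of 0.0186. Chst2 rose by 0.62 per allele (adjusted p = 0.0268), Cd22 by 0.28 (adjusted p = 0.0334) and Crlf2, a cytokine receptor gene, by 0.22 (adjusted p = 0.0379), while Nhsl2 changed by -0.35 (adjusted p = 0.0287) and Hlf by -0.34 (adjusted p = 0.0288). C9orf72 itself had a slope of -2.33 per allele and did not pass (adjusted p = 0.0541), since its steps from 0 to 1 and from 1 to 2 alleles were not of 1 size on the log2 scale. In all 26 genes passed, 9 higher and 17 lower, with 1655 at an unadjusted p under 0.05. With process day in place of sex 24 genes passed but only 5 of the 26 among them, and with day beside sex 37 passed, 11 of the 26 among them. The count was 163 with DESeq2 and 0 with every barcode, and without WT replicate 1, WT replicate 2 and WT replicate 3 it was 5, 0 and 141. It was 16 without HET replicate 3, and 4, 10 and 6 without HOMO replicates 1, 2 and 3.

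Of the 39 gene lists 12 passed camera along the alleles, 9 higher and 3 lower, and none held with an estimated correlation (adjusted p of 0.255 or more). As many lists passed in 35 of 80 groupings of the mice, the real one included. The lysosome (camera adjusted p = 4.41e-10; adjusted p = 0.470 with an estimated correlation) had 9 members past the threshold, all higher, adjusted over the list alone, with Ctsa at 0.18 per allele (adjusted p = 0.0557). The chemokine list (0.001; adjusted p = 0.255 with an estimated correlation) had 5, all lower. In the unfolded protein response list (0.00256; adjusted p = 0.660 with an estimated correlation) Chac1 fell by 1.66 per allele (adjusted p = 0.0442), at levels below 1 CPM, and 21 members did not pass. Ribosomal, oxidative phosphorylation, interferon, MHC class I and mTORC1 lists and both deposited modules were higher too, as were neutrophil markers (0.0180; adjusted p = 0.660 with an estimated correlation), and the cell cycle was lower (0.0471; adjusted p = 0.660 with an estimated correlation). With process day in the model 10 of the 12 passed, and MHC class I (adjusted p = 0.161) and the ARM module (adjusted p = 0.819) did not. Without HOMO replicate 1 the slopes of 4 neutrophil genes turned: S100a8 went from 0.46 to -0.83, Lcn2 from 0.64 to -1.01, Retnlg from 0.49 to -0.64 and Cxcr2 from 0.47 to -0.21, none of which passed.

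The make-up of the cells was compared per mouse. The interferon-response-like cluster 13 (313 cells, led by Ifit3, Ifit2 and Ifit3b) made up 1.59 ± 0.386% of retained cells in WT, 1.147 ± 0.308% in HET and 0.993 ± 0.312% in HOMO mice (mean ± SD, n = 3 each). Its slope was -0.300 percentage points per allele (exact permutation p = 0.0476, Benjamini-Hochberg 0.119 over 5 results), so it did not pass after adjustment, while the list of interferon-response genes was called higher in HOMO mice over all cells (adjusted p = 0.704 with an estimated correlation). With new clusters the slope turned to 0.0768. Within day 1 the share was 1.25% in the HOMO and 1.30% in the WT mouse, and within day 2 HOMO lay 0.0701 points above HET. Without WT replicate 2 the slope was -0.187 percentage points. The activated-response-like cluster 11 (418 cells, led by Spp1, Lpl and Lgals3) made up 1.19 ± 0.752%, 1.57 ± 0.798% and 1.97 ± 1.03% (exact permutation p = 0.276, n = 3 each). Its slope turned to -0.419 with new clusters and to -0.0165 on the logit scale with process day. Within day 1 it was 1.22% in the HOMO and 1.93% in the WT mouse.

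The baseline clusters, led by no gene above a fold of 4, made up 48.1 ± 0.854% of retained cells in WT, 45.8 ± 0.865% in HET and 43.6 ± 0.705% in HOMO mice (n = 3 each). Their slope of -2.27 percentage points per allele gave an exact permutation p of 0.00119, the smallest the 1680 arrangements allow, and a Benjamini-Hochberg value of 0.00595 over 5 results. It did not pass with new clusters (slope -6.35, exact permutation p = 0.627), but these held another set of cells. The new clusters under the same limit held 28.6% of cells in HOMO replicate 1 and 79.8 to 95.9% in the other mice. A new cluster of 2412 cells led by S100a8 and S100a9 lay outside them. That slope is therefore no like-for-like check of the baseline share. Within day 1 the HOMO share lay 5.2 points below WT and the HET share 2.05 points below; within day 2 HOMO lay 2.37 points below HET, and within day 3 HET lay 2.95 points below WT. The cells outside these clusters made up 51.9%, 54.2% and 56.4%, and they include cluster 3, whose 10 leading genes include Apoe, Chst2, Cst7 and Lyz2 and also the neutrophil genes S100a8 and S100a9 and the macrophage and platelet genes Cd209f and Pf4. Its share was 3.76 to 8.04% in WT, 3.52 to 6.66% in HET and 9.52 to 20.9% in HOMO mice, highest in HOMO replicate 1, with an edgeR log2 slope of 0.77 per allele (adjusted p = 0.226). Genes that define cluster 3 passed between genotypes, so neither its share nor the baseline share is read here as a number of cells of a type. In edgeR on cells per cluster with sex the same slope did not pass (edgeR adjusted p = 0.561). Among 15 clusters compared by number the lowest Benjamini-Hochberg value of a slope was 0.179. The deposited ARM score averaged 0.336 ± 0.0318, 0.316 ± 0.0304 and 0.378 ± 0.00920 per mouse (slope p = 0.150 by exact permutation, n = 3 each), and the deposited IRM score -0.00716, -0.00888 and 0.0127 (slope p = 0.250 by exact permutation). Without WT replicate 3 the ARM slope of 0.0327 had a permutation p of 0.0321. That mouse is the WT mouse of day 1, where the ARM score was 0.3716 in the HOMO and 0.3720 in the WT mouse. HOMO lay above HET by 0.0310 within day 1 and by 0.0562 within day 2.

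**Figure D3:**
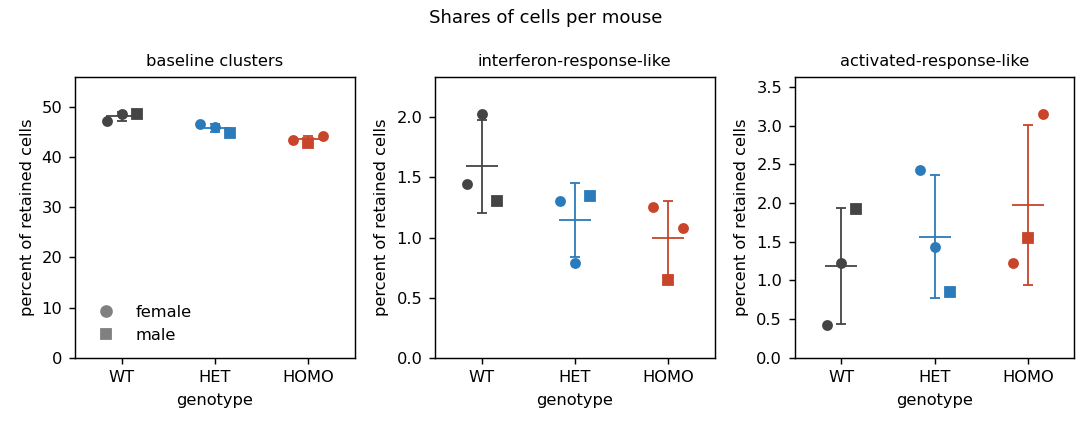
Share of retained cells (vertical axes, percent) in the baseline, interferon-response-like and activated-response-like clusters by genotype (horizontal axes). Points are mice, circles females and squares males, and bars are the mean ± SD of 3 mice; the baseline share is highest in the 3 WT mice and lowest in the 3 HOMO mice.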

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

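The fits without clusters 6, 14 and 15 were the tests chosen only after the result was seen. With 3 mice per genotype, the counts of genes past the threshold depended on single mice and on the model. For each change below the cause was not tested. In the order HOMO against WT, HET against WT, HOMO against HET, trend and baseline clusters, 30, 0, 2, 26 and 36 genes passed. DESeq2 gave 150, 9, 32, 163 and 73. No filter on low counts gave 64, 6 and 4 for the pairs and 315 in the baseline clusters. Process day in place of sex gave 60, 2 and 6 for the pairs, and day beside sex gave 80, 2 and 7, with 109 in the baseline clusters. Fits of only the groups compared gave 13 between HOMO and WT, 2 between HET and WT and 17 in the baseline clusters. In females 4 genes passed between HOMO and HET, and after thinning to equal totals 1 passed between HET and WT and 27 between HOMO and WT (25 of them among the 30). Thinning matched the totals per mouse, not the UMIs per cell. Every barcode gave 3 between HOMO and WT, 1 between HOMO and HET and 0 for the trend. Without clusters 6, 14 and 15 it was 1 between HET and WT and 4 between HOMO and HET.

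Leaving out 1 mouse at a time gave 2 to 134 genes between HOMO and WT, 0 to 2 between HET and WT, 1 to 5 between HOMO and HET, 0 to 141 for the trend and 8 to 148 in the baseline clusters. C9orf72 ranged from -8.31 to -6.92, from -0.93 to -0.85 and from -7.40 to -6.01 for the 3 pairs in the same order. Between HET and WT it was -0.91 with DESeq2, -0.904 without the filter and -0.91 with only the groups compared, and it passed in these 3. The named genes that turned did so without passing: Atf4 (0.00939 in females), Cyfip2 (0.0413 with day, 0.0119 with sex and day, -0.75 to 0.0188 leaving out 1 mouse) and Chil3 (-3.58 to 1.83 leaving out 1 mouse) between HET and WT, Stmn2 (0.26 with every barcode) between HOMO and HET, and, for the trend leaving out 1 mouse, Cxcr2 (-0.21 to 0.69), Lcn2 (-1.01 to 2.96), Retnlg (-0.64 to 1.58) and S100a8 (-0.83 to 2.18). Of 2425 values of named genes under settings other than leaving out 1 mouse, 2234 kept their direction and side of the threshold. Many of these genes had not passed in the main fit, so staying on that side says little. Of genes that passed between HOMO and WT, Bank1 and Cd22 passed in 7 of 19 alternatives, leaving out 1 mouse included. Anxa5, Cd63 and Khdrbs3 passed in 8, Ccnd1 and Chst2 in 10, Cst7 in 14, Hebp1 in 16 and C9orf72 in 19.

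With an estimated correlation 0, 0, 0 and 0 gene lists passed for the 3 pairs and the trend, and the directional fry test gave 0, 0, 0 and 0. The mixed fry test gave 18, 0 and 9 for the pairs. Leaving out 1 mouse gave 8 to 16, 3 to 12, 10 to 18 and 9 to 15 lists.

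The slope of the interferon-response-like share was -0.285 in females, 0.0768 with new clusters, -0.350 on the log2 scale in edgeR and -0.0499 on the logit scale with day, and none of these passed. The activated-response-like slope turned to -0.419 with new clusters and -0.0165 on the logit scale with day. The baseline slope was -6.35 with new clusters (exact permutation p = 0.627) and -0.0717 on the log2 scale in edgeR, and neither passed. The new baseline share was 28.6% in HOMO replicate 1 and at least 79.8% in the other mice, so it is not the same set of cells. The ARM score slope passed in females (0.0312). Leaving out 1 mouse gave slopes of -0.371 to -0.187, 0.119 to 0.565 and -2.50 to -2.13 for the interferon-response-like, activated-response-like and baseline shares, 0.00316 to 0.0158 for the IRM score and 0.0155 to 0.0327 for the ARM score. The planned share of all annotated cells was not run apart, since no cell types are given and it equals the share reported.

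A block for the replicate number gave 12 genes between HOMO and WT, 4 between HOMO and HET, 4 for the trend and 14 in the baseline clusters. The numbers do not pair the mice: mice with the same number correlated at -0.19 on average over 8013 genes, and other mice at 0.09. Mice of the same process day correlated at 0.18 on average (-0.52 to 0.48 over 7 pairs) and other mice at -0.07. Mice of the same sex correlated at -0.12 and other mice at 0.15.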

Other observations

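The splits of the mice for genes over all cells, and the tests of process day, RNA of other cell types, strain background and flanking DNA, were tests chosen only after the result was seen.

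A pair of neighbouring transcripts on chromosome 5 was nearly absent from HOMO mice, and both were singled out after their values were seen. The provisional gene Gm15446 (109923400 to 109943936) was at 4.63, 4.81 and 5.25 CPM in the WT mice, 0.162, 2.65 and 2.56 CPM in the HET mice and 0.209, 0.166 and 0.293 CPM in the HOMO mice (log2 fold change -4.45 between HOMO and WT). Its neighbour 1010001B22Rik (109995511 to 109996398) had the same order (log2 fold change -4.23), and in both HET replicate 1 lay at the HOMO level. Crlf2 (109554709 to 109558993), which passed for the trend and in the baseline clusters, lies on the same chromosome near them. The locus is on another chromosome than C9orf72. Ide, a member of the list of C57BL/6 substrain differences, lay at 26.8 to 32.1 CPM in WT, 21.7 to 23.5 CPM in HET and 18.3 to 20.7 CPM in HOMO mice. Fgfbp3, another member, starts at 36917550 on chromosome 19, where Ide starts at 37268743. It was at 0.958 ± 0.496 CPM in HET and 1.81 ± 0.193 CPM in WT mice (log2 fold change -0.99), without passing (adjusted p = 0.954). Between HOMO and WT, 5 of 6 measured members of the list were lower (camera adjusted p = 0.0715).

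The genes past the threshold between HOMO and WT mice could reflect genotype, the grouping of the mice, process day or RNA of other cells. Of the 10 splits of these 6 mice the real one had the most genes (1 of 10 with as many; 30 against at most 2 in another), and 10 splits are too few to decide. With process day beside sex the median ratio of the log2 fold changes was 1.01 (quartiles 0.928 to 1.09). Only 19 of 30 still passed, with a median SE of 0.108 against 0.104. The 30 genes were called from the same mice, and the call favours genes with little spread between the mice of a genotype. WT and HOMO mice were each split over days, so the call tended to leave out genes that shifted between days. The median ratio was therefore partly set by the selection and cannot decide on process day. With day in place of sex 14 of 30 passed, so process day stays open as a cause. Without clusters led by markers of other cells the median ratio was 0.989 and 27 of 30 passed. Most of the cells left out (1998 of 2313) were of cluster 6, led by erythroid genes, where microglia markers averaged a log2 of 0.333 over all cells. That fit thus left out mainly cells with microglia markers, and it left free RNA of other cells in the other clusters. RNA of other cell types cannot be told apart from genotype here. An effect of genotype stays open beside differences between the mice other than genotype.

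The same test of splits was run on the other results. Between HET and WT 0 genes passed in the real grouping, so all 10 of 10 splits had as many (at most 2 in another) and that test decides nothing. As many genes as in the real grouping passed in 3 of 10 between HOMO and HET (2 real, at most 3) and in 1 of 10 in the baseline clusters (36 real, at most 5). As many gene lists passed in 5 of 10 splits between HOMO and WT (11 real, at most 13), in 9 of 10 between HET and WT (8 real, at most 16) and in 1 of 10 between HOMO and HET (17 real, at most 15). For lists between HOMO and WT and between HET and WT, other splits thus gave as many. A list past the threshold there may come from how mice happened to be grouped. Other splits also gave as many genes between HOMO and HET. For the counts reached in 1 of 10, the 10 splits are too few to decide. For the trend, of 80 groupings (the real one and others drawn at random from the 1680) 1 had as many genes (26 real, at most 11 in another drawn). The draws were not held to 2 females and 1 male per genotype, as the real grouping is, and sex was in the fit. The comparison can therefore favour the real grouping, and it does not settle whether random grouping of the mice gave the count. These fits leave out process day, and only 11 of the 26 genes passed with day beside sex and 5 with day in place of sex, so day stays open there. For the trend in gene lists 35 of 80 had as many (12 real, at most 16), so a list past the threshold there may come from how mice happened to be grouped.

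Called genes lying close to another called gene could mark DNA of another strain carried by some mice, or DNA around the targeted allele. There were 4 of them among 29, against a mean of 1.48 in 10000 random draws, and a share of 0.159 of the draws had as many, so strain background cannot be told apart from random placement, since the pairs are few and 1 pair, Bank1 and Gm31243, overlaps. Crlf2, and Fgfbp3 near Ide, were not counted, as they did not pass between HOMO and WT over all cells. The 4 neighbouring genes lie on chromosomes 3 and 5, and C9orf72 lies on chromosome 4. Their positions were known before the flank of C9orf72 was counted, so the count of 0 of them there tests nothing. Of 85 genes tested in that flank 10.6% had an unadjusted p under 0.05, against 13% of all genes, so small p-values were not more frequent there. So few genes cannot decide whether flanking DNA changed single genes, which stays open. Whether the mice differ in strain at the chromosome 5 locus stays open, as no genotypes are given.

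Neutrophil transcripts in HOMO replicate 1 could come from free RNA in the droplets, from whole neutrophils among the cells or from expression in microglia. S100a8 and S100a9 stood at 358 to 453 CPM in each of the 14 clusters with at least 30 cells of that mouse, and the median over clusters was 1.03 times the level over all cells, which free RNA would give. The 1% of cells with the most of these UMIs held 4.98% of them, which argues against whole neutrophils among the cells. WT replicate 2 showed the same spread at 196 to 267 CPM, so the level is not tied to genotype. In the barcodes outside the retained cells, neutrophil markers were at 65664 CPM in HOMO replicate 1 and 67364 CPM in WT replicate 2, against 2383 to 9056 CPM in the other 7 mice; expression in microglia was not tested.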
